A study of Homo sapiens with 4 samples.

How the data were processed

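H3K27ac, the acetylated form of lysine 27 of histone H3 found at active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing in C4-2B cells. C4-2B is a castration-resistant human prostate cancer cell line derived from LNCaP. There was 1 H3K27ac library from cells given YDGY-3 at 20 nM for 24 h and 1 from control cells. Each had an input library, sequenced chromatin without antibody, which enters here only through the peak caller. Samples were grouped by their titles. The labels disagree about the control: its own treatment label says untreated, the text of the series names DMSO, and a treatment note shared by all samples describes the compound. The control is called untreated throughout, and the vehicle is left open.

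Per the labels' protocols, nuclei were sonicated, fragments of the selected size were cut from a gel after PCR, and libraries were sequenced on a BGISEQ-500. Per the submitters' processing notes, the build was hg19 (GRCh37) and CASAVA 1.4, MACS2 and bedtools were used; the aligner is not given in the sources used here. Per the file headers, peaks were called with MACS 2.1.4, separately for each ChIP library against its own input, as narrow peaks at a q-value cutoff of 0.05. Per the file headers, reads were 50 bp single-end tags, no more than 1 tag was kept per position, and the larger of ChIP and input was scaled to the smaller. The headers also give the fragment length to which each tag was extended. The caller estimated 156 bp in the treated library and 49 bp in the untreated library, where the value lies next to the tag size. For the untreated library the header lists 161, 197, 497 and 566 bp as other candidates. The fragment length sets how many tags pile up over a base and the minimum peak width, so pileups and widths of the 2 lists are not on one scale.

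The deposited tables give, per peak, the 1-based position, the width, the pileup signal at the summit, the fold enrichment over the local input, and 2 columns whose header text was lost in a spreadsheet. These were read as the authors' −log10 p-value and −log10 q-value by their place in the caller's output. The first exceeded the second in 26820 of 26820 treated and 291 of 291 untreated peaks. Fold, p and q are the authors' values and were used to describe, rank or filter peaks within a list, with 3 exceptions. Folds of overlapping peaks were correlated between the lists, the treated list was also limited at the smallest −log10 p-value of the untreated list, and untreated q-values gave an allowed number of false calls.

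Dividing each pileup by the scaling factor from the header gave whole fragments in 100.00% of the peaks of both lists, with a tolerance of 0.02 fragments. The local input level was recovered from the fold with the caller's pseudocount of 1. Poisson p-values recomputed from these numbers differed from the deposited −log10 p-values by at most 0.00537. That pseudocount lowers the fold more where the fragment length is shorter, so folds are not on one scale between the lists either. Fragments at a summit are given with exact Poisson 95% intervals and shares of peaks with exact Clopper-Pearson 95% intervals. Both cover counting error only. After duplicate filtering the ChIP libraries held 24426244 (treated) and 24685614 (untreated) tags, and their inputs 24387350 and 24487301.

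With 1 library per group no difference has a replicate check, and no p-value is given for the treatment. Peaks were compared by overlap of at least 1 bp with bedtools 2.31.1. The overlap was set beside 1000 random placements of the untreated peaks on their own chromosomes within the span of the treated peaks. Peaks within 12 kb were stitched into regions. Before the data were examined, the regions to be named were fixed as the 10 highest folds of each list, the 5 widest stitched regions, the 10 shared peaks with the highest untreated fold and up to 10 untreated peaks without a treated partner. Alternatives fixed at the same time were stricter q and fold limits, other overlap rules, merging within 1000 bp, stitching within 5 kb and chromosomes 1 to 22 and X alone. The overlap and repeat-spacing functions were tested on simulated data: 200 of 200 planted overlaps were recovered and 0 of 100 planted outside treated peaks were called. A planted spacing of 3000 bp was found when spacings from 2000 bp alone were searched. The search from 1000 bp, used for the regions below except where stated, was not tested in this way. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

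The gene table at hand is on GRCh38, another build, and coordinates were not converted. Positions below are therefore given on hg19 without genes, and 2 planned results, the annotation of peaks to promoters and the promoter marks of 18 gene lists, were not analysed here. The genes fixed for naming were left out for the same reason.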

Results

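The series compared H3K27ac, a mark of active promoters and enhancers, between C4-2B prostate cancer cells exposed to YDGY-3 at 20 nM for 24 h and control cells labelled untreated. Its title concerns inhibitors of importin-β1, a carrier that moves proteins into the nucleus. Each condition had 1 H3K27ac library, called against its own input. The treated library held 24426244 filtered ChIP tags and the untreated library 24685614, a ratio of 0.989. All values below therefore describe 2 libraries, without replicate error, and a site that is not in a list was not called, which does not show that it lacked the mark.

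H3K27ac peaks were far more numerous in the treated library. It had 26820 peaks covering 11.4 Mb, against 291 peaks covering 21.7 kb in the untreated library, 92.2 times as many peaks. The median treated peak was 318 bp wide with 17 fragments at its summit, and the median untreated peak was 65 bp wide with 10 fragments. Median fold enrichment over the local input was 6.25 in the treated list (quartiles 5.10 and 8.29) and 7.04 in the untreated list (quartiles 6.19 and 7.74). The caller had extended tags to 156 bp in the treated and 49 bp in the untreated library, a ratio of 3.18, so widths, fragments and folds of the lists were not measured on one scale. The weakest called peak had a −log10 p-value of 3.72 in the treated list and 6.03 in the untreated list.

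The untreated peaks lay almost entirely at sites called in the treated library. Of the 291 untreated peaks, 276 (94.8%, 95% interval 91.6 to 97.1%) overlapped a treated peak, and random placement gave a mean of 1.98 and at most 7 in 1000 placements. In the other direction, 256 of the 26820 treated peaks (0.955%, 0.842 to 1.08%) had an untreated partner. These 256 were stronger and wider at the median than the rest of the treated list, although they went down to a fold of 2.59. Their median fold was 11.2 and their median width 809 bp, against 6.24 and 316 bp for the 26564 without a partner. The share with a partner was 0.0575% among treated peaks of 8 to 15 fragments (0.0211 to 0.125%), 1.97% at 26 to 30 fragments (1.45 to 2.61%), 12.3% at 41 to 50 fragments (9.11 to 16.1%) and 13 of 26 above 60 fragments (29.9 to 70.1%).

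**Figure D1:**
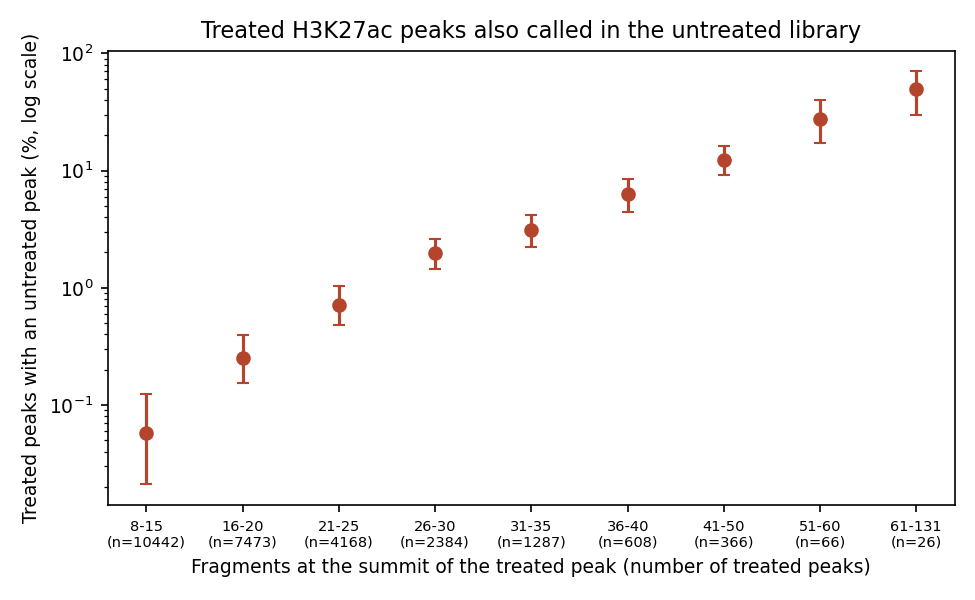
Share of treated H3K27ac peaks that overlapped an untreated peak (percent, log axis) by the number of fragments at the treated summit; points are shares and bars exact 95% intervals for counting error, with the number of treated peaks under each class. The share went from 0.0575% in the weakest class to 13 of 26 peaks in the strongest.

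Where both libraries had a peak, their summits lay a median of 77 bp apart. Over the 276 overlapping pairs the median fold was 11.3 in the treated list and 7.06 in the untreated list, each on its own scale. Per 100 bp of fragment length the median was 21.8 treated and 20.4 untreated fragments, and in the 98 pairs with 40 or more treated fragments the median ratio of untreated to treated was 0.707 (quartiles 0.621 and 0.814). Every pair needed an untreated call, which sets a lower limit on the untreated value, and the 98 pairs were chosen for high treated counts. A summit counted over 49 bp is also a narrower maximum than one over 156 bp. These densities therefore do not measure the difference between the libraries, at these sites or over all treated sites. Of 2 relations computed across the 276 pairs, which are sites and not independent replicates, the folds gave a Spearman's rho of 0.104 and a Pearson's r of 0.0975, and the fragments at the summit a rho of 0.297 and an r of 0.691. The pairs held 256 treated peaks, so some treated peaks were counted more than once. The treated peak with the most fragments, 131 on chromosome X, was paired with untreated peaks of 39, 58 and 60 fragments. The medians were 34 treated and 10 untreated fragments. Such extreme pairs weigh heavily in r, which was not recomputed without them.

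The strongest treated site lay on chromosome 14 at 35025562 to 35025968, with 67 fragments (95% interval 51.9 to 85.1), 28.2-fold over input. The untreated library also had a peak there, at 35025669 to 35025888, with 14 fragments (7.65 to 23.5) and a fold of 9.99, counted over a fragment length of 49 instead of 156 bp. Next came chromosome 5 at 137910173 to 137911376 with a fold of 25.7, chromosome 3 at 176911281 to 176917041 with 23.6 and chromosome 11 at 65479425 to 65479986 with 23.5, each without an untreated peak. Chromosome 10 at 32635343 to 32636525 had a fold of 23.01, and the untreated peak within it, at 32635794 to 32635998, 10.3. Chromosome 17 at 1619850 to 1620871 reached 22.6-fold and chromosome 9 at 132244276 to 132247286 22.4-fold, with untreated folds of 7.28 and 7.74 inside them. On chromosome 1, the sites at 1623262 to 1624603 and at 16993434 to 16994043 both reached 21.6-fold, and the second held an untreated peak of 6.95-fold. The tenth, on chromosome 20 at 60717585 to 60719355, had a fold of 21.5 and no untreated peak. In all, 5 of these 10 sites, 20 of the highest 100 (12.7 to 29.2%) and 88 of the highest 1000 (7.12 to 10.7%) had an untreated partner.

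The strongest untreated sites were partly others, and several had high input. The highest untreated folds were 15.5 on chromosome X at 115005062 to 115005133, 12.9 on chromosome 3 at 73159922 to 73159971, 11.7 on chromosome X at 115004850 to 115004929 and 11.2 on chromosome 1 at 145382546 to 145382602. In the treated list the fold at these places was 8.79 for the single peak that spans both X sites, 6.72 and 9.59. The local input under those treated summits was 14, 10 and 4 fragments, against a genome background of 1.41. The other 6 of the 10 highest untreated sites had folds from 9.99 to 10.3. One was a further X peak at 115004671 to 115004747, inside the same treated peak as the X sites above. Its local untreated input was 5 fragments, against a background of 0.444. The rest were the chromosome 10 and chromosome 14 sites given above, chromosome 14 at 39736396 to 39736475, chromosome 3 at 50329569 to 50329626 and chromosome 1 at 149224338 to 149224442. The last 3 lay in treated peaks with folds of 15.2, 12.9 and 21.0. All of these 10 sites overlapped a treated peak, so they are also the 10 shared sites with the highest untreated fold.

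Many treated peaks lay near others, and most of the length of the 5 widest regions stitched within 12 kb was gaps between peaks. Stitching within 12 kb gave 12315 treated regions, of which 5872 (47.7%) were single peaks and 183 held 10 or more peaks. The widest were on chromosome 22 at 36724253 to 36793301 (69.0 kb, 35 peaks), chromosome 15 at 89630808 to 89694495 (63.7 kb, 52 peaks), chromosome 16 at 685573 to 745755 (60.2 kb, 17 peaks), chromosome 22 at 43317571 to 43375318 (57.7 kb, 23 peaks) and chromosome 4 at 77598411 to 77653295 (54.9 kb, 15 peaks). Peaks covered 19.8, 25.4, 8.32, 8.55 and 5.64 kb of them, in that order. None of these 5 regions held an untreated peak, while 23 of the 183 regions with 10 or more peaks did. The 0 of 5 depended on the stitching distance: within 5 kb, the 5 widest treated regions included those on chromosomes 21, 22 and X that held 2, 8 and 15 untreated peaks. Treated peaks covered 27.1 of 51.8 kb, 38.5 of 51.1 kb and 39.2 of 49.4 kb of these 3.

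The untreated library formed 241 stitched regions, 211 of them single peaks. Its widest lay on chromosome X at 114960666 to 115005133 (44.5 kb, 15 peaks) and on chromosome 22 at 46451830 to 46470737 (18.9 kb, 7 peaks), where the treated library had 37 and 14 peaks. The next were on chromosome 21 at 17680567 to 17692303, chromosome 14 at 35015613 to 35025888 and chromosome 22 at 50344615 to 50354682, each with 2 untreated peaks and with 8, 2 and 3 treated peaks.

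**Figure D2:**
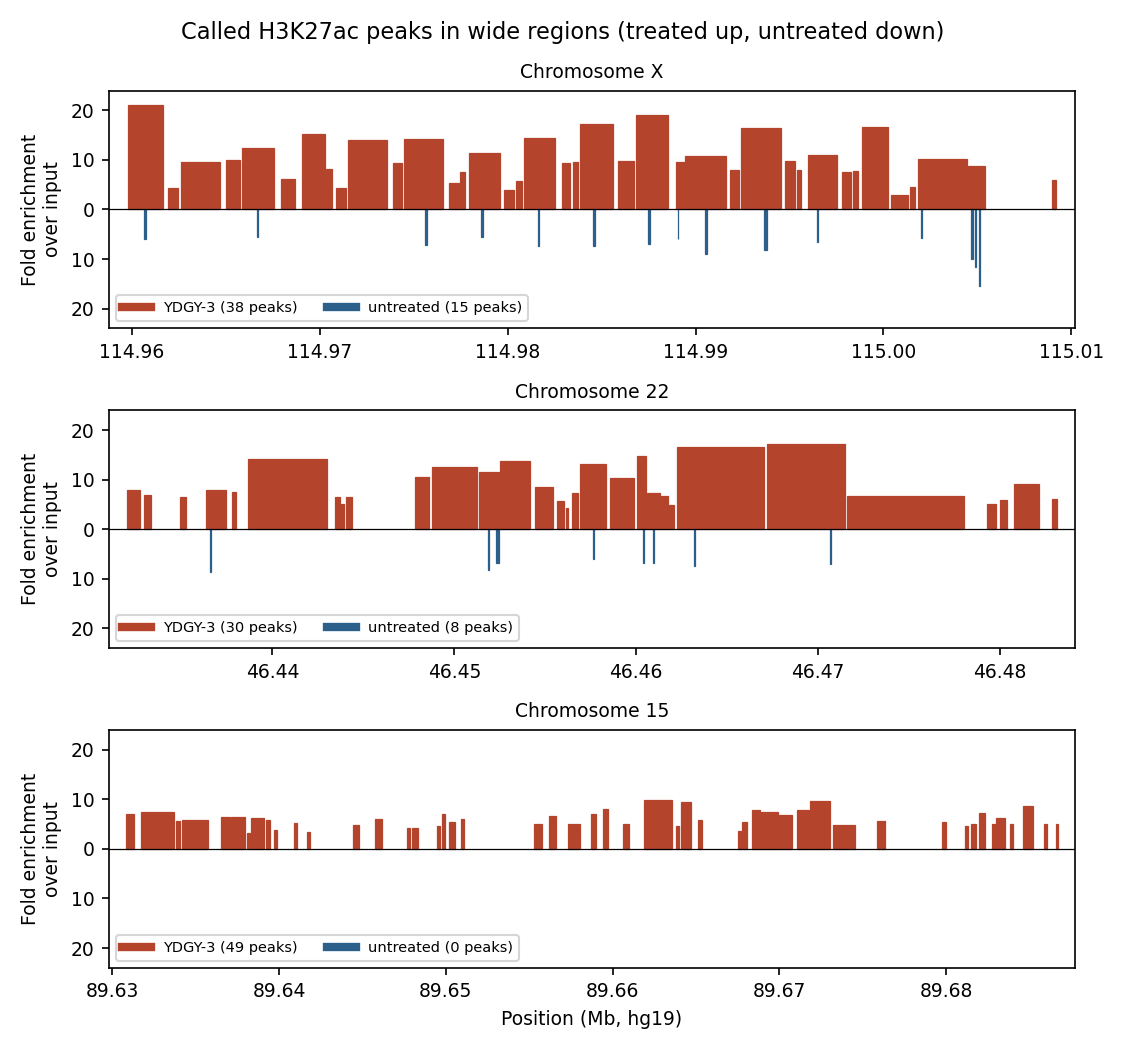
Called peaks in 3 wide treated regions (stitched within 5 kb) on chromosomes X, 22 and 15: each block spans a peak on hg19 (Mb), and its height is the authors' fold enrichment over input, treated upward and untreated downward. The X region held 38 treated and 15 untreated peaks, the chromosome 22 region 30 and 8, and the chromosome 15 region 49 and 0.

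The 95% intervals for the share of peaks on a chromosome were apart between the libraries for 3 of 23 chromosomes, with no allowance for the number compared. For the others the untreated counts were often too small to tell, as on chromosome 18, with 1.64% of treated peaks and 0.344% of untreated peaks (1 peak). Chromosome 2 held 5.44% of treated peaks (5.18 to 5.72%) and 1.72% of untreated peaks (0.560 to 3.96%). Chromosome 22 held 3.39% (3.18 to 3.61%) and 6.19% (3.71 to 9.60%), and chromosome X 1.91% (1.75 to 2.08%) and 5.15% (2.91 to 8.36%). The higher untreated shares on the latter 2 rested on single regions, chosen after the values were seen. Without the region at 46432020 to 46483128, chromosome 22 held 3.28% of treated and 3.53% of untreated peaks (1.71 to 6.40%). All 15 untreated X peaks lay in the region at 114959802 to 115009187. Outside it the X chromosome had 475 of 26782 treated peaks (1.77%, 1.62 to 1.94%) and, by the choice of the region, 0 of the other 276 untreated peaks. These intervals treat peaks as independent, and neighbouring peaks are not. The untreated peaks also lay mostly at stronger treated sites, and the chromosome shares of those sites alone were not compared.

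**Figure D3:**
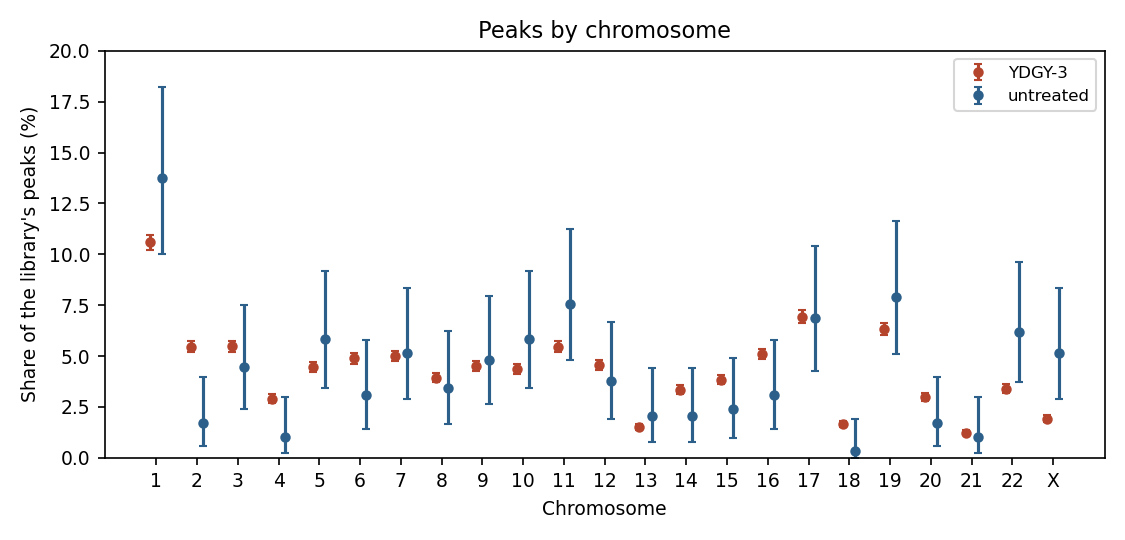
Share of each library's peaks by chromosome (percent of the library's peaks), with exact 95% intervals for counting error as bars, treated and untreated side by side. The intervals are apart for chromosomes 2, 22 and X.

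The untreated library had 15 peaks without a treated partner, none of them among its 10 highest folds. Their folds ran from 5.64 to 8.66 and their median −log10 q-value was 3.09, against 3.56 for the 276 shared untreated peaks. The highest were on chromosome 8 at 81491070 to 81491245 with 12 fragments (6.20 to 21.0) and a fold of 8.66, chromosome 19 at 51373334 to 51373465 with 11 fragments (5.49 to 19.7) and 8.25, and chromosome 3 at 175030974 to 175031048 with 11 fragments and 7.97. The nearest treated peaks were 91.4, 2.59 and 34.0 kb away. The next 7 had folds from 6.56 to 7.56. They lay on chromosome 6 at 34522268 to 34522316, chromosome 5 at 139702534 to 139702582 and at 176830249 to 176830333, chromosome 15 at 70387401 to 70387453, chromosome 4 at 77136778 to 77136869 and at 171010938 to 171010986, and chromosome 9 at 79413933 to 79414011. Of the 15 sites, 6 lay within 1000 bp of a treated peak.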

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

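Of 48 alternative values for 12 results, 31 stayed within 1.5 times the reported value, and the treated library had more peaks than the untreated library under each alternative run for that ratio. Stricter limits remove peaks by construction: at a −log10 q of at least 5 the untreated list fell to 62 peaks and 5230 bp and the ratio of peak numbers rose to 318.32; at 10 the lists held 9740 and 6 peaks, a ratio of 1623.33. Merging peaks within 1000 bp left 15741 treated peaks and a ratio of 58.96. Of the 276 untreated peaks in a treated peak, 2 met a reciprocal overlap of 50%, since the median widths of 65 and 318 bp rarely allow it; 60 of 62 remained with both lists at a −log10 q of at least 5, and 61 lay in the 291 treated peaks with the highest −log10 q. For the 256 treated peaks with a partner the same settings gave 2, 56 and 52, and counting neighbours within 1000 bp gave 486. That setting left 9 of the 15 untreated sites without a treated partner. Stitching within 5 kb narrowed the widest untreated region from 44.5 to 20.9 kb and the widest treated region from 69.0 to 55.9 kb. It left 1 of the 5 widest treated regions, on chromosome 15, among the 5 widest, and put regions with 2, 8 and 15 untreated peaks beside it. The alternatives chosen after seeing the data were the untreated p-value limit, no X region and widened untreated peaks. Each was run for some of the peak numbers and overlaps, the widened peaks for overlaps only. None of the values run moved by over 1.5 times, although the untreated X share went from 5.15% to 0 without its region. The untreated p-value limit was met by 24442 treated peaks, and without the X region the ratio of peak numbers was 97.0. No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. The promoter and gene list alternatives were not run. No untreated summit had under 7 fragments, so weaker sites were not called there at this depth, fragment length and q-value cutoff. The weakest called peak had a −log10 p-value of 6.03 there and 3.72 in the treated list, so the cutoff was stricter for the untreated library.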

Other observations

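All tests of explanations in this part were chosen only after the results had been seen.

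Among classes of width, the widest treated peaks were few and had an untreated peak most often. Treated peaks of over 1000 and up to 2000 bp were 4.83% of the list and 14.6% of its covered bases, and wider ones 0.623% and 3.89%. The untreated library had a peak in 5.63% (4.44 to 7.03%) of the former and 15.6% (10.4 to 21.97%) of the latter, against 0.144% of treated peaks up to 300 bp (0.0854 to 0.228%). Width mostly went with strength, from a median of 213 bp at 8 to 15 summit fragments to 1081 bp at 51 to 60 and 916 bp above 60, so the width classes do not show an effect of width itself.

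The first pattern is the gap between 26820 treated and 291 untreated peaks. Sequencing depth was argued against by the filtered ChIP tags, in a ratio of 0.989. The short fragment length of the untreated call was weighed at the treated tag density with the untreated cutoff kept. The number of treated peaks it would leave called was set beside the 256 that were called. At the measured fragments it would leave 7912 with tags spread evenly and 1069 in the least favourable arrangement. With each peak at its lower counting bound the numbers were 2550 and 229. Only the 229, from the setting least favourable in both respects, fell below 256. Among the 106 treated peaks of 50 or more fragments, 33 were called. There the least favourable arrangement gave 55 at the measured fragments and 27 at the lower bound, and the even one 103 and 93. These numbers rest on assumed arrangements of tags and on summits chosen for being high. They also rest on the kept cutoff, where the weakest untreated peak had a −log10 p-value of 6.03, against 3.72 in the treated list. A q-value cutoff becomes less strict as more positions are enriched, so at the treated density the numbers may be too low. The explanation therefore stays open, but even with the cutoff kept it reached the observed number only at that extreme. Weaker immunoprecipitation of the untreated library and a gain of H3K27ac under YDGY-3 cannot be told apart with 1 library per group, since either may leave calls at the strongest treated sites (0.0575% called at 15 or fewer fragments, 50% above 60).

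The second pattern is the chromosome X region at 114959802 to 115009187, which held 15 of 15 untreated X peaks. Its 38 treated summits fell on a shared phase at a spacing of 1500 bp, with a phase concentration of 0.584, where 1 is perfect, against a 95th percentile of 0.440 for random positions and at most 0.445 in the other 4 of the 5 widest treated regions stitched within 5 kb. The untreated summits gave 0.783 at 2950 bp (random 0.671), and the 17 treated summits of 40 or more fragments 0.722 at 2970 bp (random 0.611) when spacings from 2000 bp alone were searched. These come largely from the same sites and are not separate evidence. Positions spaced at a whole multiple of 1500 bp also share a phase at 1500 bp, so the length of a repeated unit was not settled. Summits of separate peaks, which covered 39.2 of 49.4 kb here, cannot lie as close as random positions can. The chromosome 22 region, covered over 38.5 of 51.1 kb, gave 0.322 from 30 summits (random 0.491). The 0.445 came from 16 summits (random 0.649), so concentrations of different regions are not on one scale. A candidate explanation is a tandem array whose copies each carry the mark or share reads; the sequence was not analysed here. Raised input, 2.13 times background under the treated and 1.88 times under the untreated peaks, stays open: the median fold was 9.65 against 6.25 over the treated list but 7.10 against 7.04 over the untreated list, and listed peaks had to be enriched over the local input to be called.

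The third pattern is the 15 untreated sites without a treated peak. The weakest of them had a q-value of 0.00853, which taken over 266 untreated peaks would allow 2.27 false calls, fewer than the 15 found. That number counts peaks, while the caller adjusts q-values over positions of the genome. It also rests on the caller's model with a fragment length of 49 bp. False calls are therefore not excluded. Of the 15 sites, 6 lay within 1000 bp of a treated peak, where random placement gave a mean of 0.223. Treated signal just beyond a called edge may account for some. Random positions were drawn evenly along each chromosome, however, so nearness alone cannot tell this from other sources of calls near treated peaks. The cause stays open for all 15, including the chromosome 8 site with no treated peak within 91.4 kb.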
